A study of Sus scrofa with 8 samples.

How the data were processed

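Liver RNA from 8 Iberian pigs (Sus scrofa), taken at slaughter at 211 days of age, was hybridised as biotin-labelled cRNA to an Affymetrix porcine expression array, 1 array per animal. The animals formed a layout of sex by feeding level with 2 animals in each of 4 groups. The groups were males and females on the high feeding level and males and females under 25% restriction, called restricted here. Groups were taken from the labels, and each array was a separate animal with its own number, so nothing paired the samples. The labels did not say whether animals shared a litter, a pen or a day of processing.

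The deposited table held log2 expression values for 24123 probe sets on each of the 8 arrays, and the authors made them with GCRMA, per the submitters' processing notes. GCRMA corrects the background with probe sequence, normalizes between arrays by quantiles and summarises the probes of a set. Its version, the scanner software and any genome build were not given in the sources used here. The log2 values ran from 0.99 to 15.54, with no missing value. No further normalization was applied, because GCRMA values are already normalized between arrays. The array medians lay between 3.74 and 3.77. Values near the low end of a GCRMA scale are compressed towards background, so large differences with 1 side near log2 2 to 4 have an uncertain size. The number of arrays limits the precision of every value below.

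Of the probe sets, 124 were array controls and were left out of the tests. A probe set was kept when its log2 value was above 4 on at least 2 of the 8 arrays, which left 11927 of 23999. Gene symbols came from the platform annotation supplied with the series, looked up by Entrez identifier in a current RefSeq gene table, which held 9989 of the identifiers and changed 0 symbols. In the table, 10099 probe sets had 1 symbol, 198 had several and 13826 had none here. Among kept probe sets, 6090 had 1 symbol, 133 several and 5704 none, and the first kind covered 4757 genes. Genes were named only from probe sets with 1 symbol. Several fixed list members were found only through a synonym in the RefSeq table, such as SULT1A3 for SULT1A1 and CYP2A19 for CYP2A6. The table also gave NIFK for MKI67, although NIFK is a binding partner of the protein MKI67. Probe sets of related enzymes can share sequence, which was not examined.

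Tests used limma 3.58.1 in R 4.3.3. A model with 1 mean per group was fitted to all 8 arrays (lmFit, 4 residual degrees of freedom), contrasts were formed, and eBayes moderated the variances with 2.8 prior degrees of freedom. The p-values were adjusted by Benjamini-Hochberg over the kept probe sets within a contrast, with a threshold of 0.05. The 7 contrasts were the sex effect (male minus female, averaged over feeding), the feeding effect (restricted minus high, averaged over sex), their interaction (the feeding difference in males minus that in females), feeding within each sex, and sex within each feeding level. Every adjusted p below is limma's unless another test is named. The ± after a log2 difference is limma's moderated standard error.

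Before the data were examined, 35 gene lists were fixed, covering metabolic pathways, hormone response, plasma proteins, stress and immune genes and markers of other cell types. With 1 probe set per gene (the one with the highest mean), 29 lists had at least 5 measured genes and were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast. Camera asks whether a list's genes are shifted relative to the other genes. The same lists were tested with an estimated correlation and with fry, whose p-value asks whether a list's genes move, on balance, one way. For some lists the median, the mean and the direction given by camera had different signs: 7 of 29 for sex, 7 for feeding and 4 for the interaction. None of those lists passed the threshold.

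Most genes named below followed a rule also fixed before the data were examined. For sex and for feeding, up to 12 genes each way were taken, those with the largest log2 difference that passed the threshold, had no overlap between the 4 arrays of each side and came from a probe set with 1 symbol. The other contrasts gave up to 5 each way. Where fewer than 12 genes passed, the 8 genes with the largest difference at an unadjusted p under 0.001 were given as values that did not pass. From each list, up to 4 members with the smallest p were open to naming, and all measured members of the lists of Y-linked genes and their X partners. No gene so named for sex or feeding had another kept probe set with the opposite sign at an unadjusted p under 0.05.

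The procedure was tested on simulated data with the real means, limma's moderated variances and independent noise. Each of 5 runs held 11927 probe sets, of which 200 were changed. For the sex effect, 82.4% of changes of 1 on the log2 scale were recovered and 97.6% of changes of 2. For the feeding effect the shares were 83.2% and 97.6%, for feeding within males 35.2% and 92.2%, and for the interaction 2.6% and 68.8%. In 20 simulated sets of 29 lists of independent genes, camera called a list of 25 genes shifted by 0.3 in 20 sets and called 0 of 560 unshifted lists. Real genes are correlated, which both simulations left out, so the shares recovered need not hold for the real data.

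The alternatives were no filter, a filter at log2 6, added quantile normalization, median centring, a model without the interaction, a fit without the other factor, eBayes with trend and robust settings, array weights, 1 probe set per gene, other gene list tests, and each animal left out in turn. Figures were drawn with matplotlib 3.10.9. No coordinates are given, since no build was named.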

Results

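Gene expression was measured in the liver of 8 pigs, 4 males and 4 females, with 4 animals fed at the high level and 4 under 25% restriction. The series compares hepatic expression between the sexes and between the feeding levels. On each array between 47.4% and 47.8% of probe sets lay above log2 4. Arrays of the same group correlated at 0.9678 to 0.9826 over the kept probe sets. Arrays of the same sex at different feeding levels reached 0.9626 to 0.9814, and no pair of arrays shared more than 2 identical values. The first principal component held 44.0% of the variance and placed the 4 males between -34.7 and -21.4 and the 4 females between 25.7 and 33.1. The second held 17.5%.

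**Figure D1:**
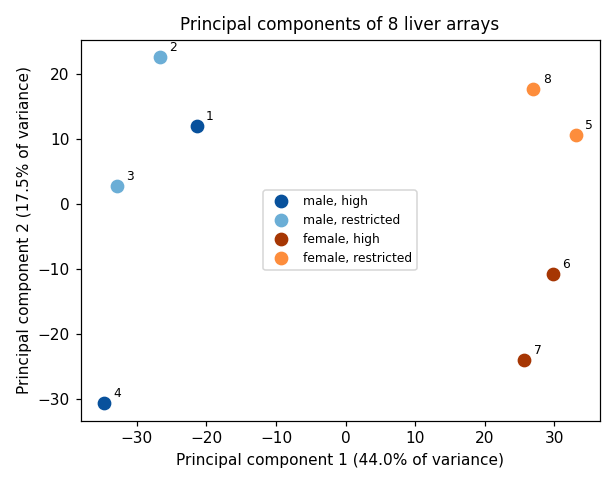
Scores of the 8 arrays on principal components 1 (44.0% of variance) and 2 (17.5%), 1 point per animal, coloured by group and numbered by animal. Males lie at or below -21.4 on the first component and females at or above 25.7.

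The labels of sex were first set against genes of the sex chromosomes. EIF1AY, a Y-linked translation factor, had a log2 value of 8.94 ± 0.23 in males and 2.85 ± 0.03 in females (SD, n = 4 each). It was the only member of the list of Y-linked genes that was measured. KDM6A, an X-linked histone demethylase with a Y partner, was lower in males by a log2 difference of -1.02 ± 0.20 (adjusted p = 0.0376). Its list mates EIF1AX (-0.33), TXLNG (-0.38) and USP9X (-0.11) also had values below 0 and did not pass.

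The genes with the largest differences between males and females included P450, steroid and carbonyl enzymes, although camera called no list. CYP2C36, a cytochrome P450, had a log2 value of 13.57 ± 0.26 in males and 5.87 ± 1.0 in females (SD, n = 4 each), a difference of 7.70 ± 0.49 (adjusted p = 0.000707). In the other direction, HSD17B2, which oxidises oestradiol and testosterone to weaker steroids, was at 3.02 ± 0.55 in males and 10.93 ± 1.14 in females, a difference of -7.91 ± 0.46 (adjusted p = 0.000485). CYP2A19, a P450 that acts on skatole, was lower in males by a difference of -6.75 ± 0.43 (adjusted p = 0.000707). In all, 619 probe sets passed the threshold, 311 higher and 308 lower in males, and 300 of them named 1 gene each (140 genes higher and 133 lower). Of the 619, 341 differed by more than 1 on the log2 scale. Over all 11927 probe sets kept, called or not, the 4 males did not overlap the 4 females in 12.5%, where chance gives 2.9%.

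The carbonyl reductases CBR2 (log2 difference 8.02) and CBR1 (6.70) and the short-chain dehydrogenase DHRS4 (2.90) were higher in males. So were the P450 CYP2B22 (4.03), the serine dehydratase SDS (4.14), the neuronal growth protein NRN1 (4.51), the glutamate transporter SLC1A2 (2.97), the transcription factor subunit GTF2F2 (2.95), the caveolin CAV2 (2.77) and the mitochondrial carrier SLC25A33 (2.67). CBR2, CBR1 and NRN1 varied widely among males, with SDs of 2.75, 2.75 and 2.40, and of 4.23, 3.91 and 3.22 within the high-fed males. Their calls were kept without male_high replicate 1 or male_high replicate 4 and lost without any of the other 6 animals, and the lowest differences with 1 animal left out were 6.52, 5.32 and 3.37. CAV2 kept its call only without male_high replicate 1, SLC25A33 only without male_high replicate 1, male_low replicate 3 or male_high replicate 4, and SLC1A2 lost it without male_low replicate 2, male_low replicate 3, female_high replicate 6 or female_high replicate 7. Their lowest differences were 2.20, 2.24 and 2.47. A fit without a high-fed male holds 1 array of that group, so the spread within the group leaves the variance. A call kept in such a fit does not show stability.

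Lower in males were the carbonic anhydrase CA3 (log2 difference -5.09), the flavin monooxygenase FMO5 (-4.97), the sulfotransferase SULT1A3 (-4.20), and MIOX (-3.49), which starts the breakdown of inositol. The carrier SLC25A48 (-3.49), the thiolase ACAA2 (-3.37), the oviductal glycoprotein gene OVGP1 (-3.19), the quinone reductase NQO1 (-3.15), ENC1 (-2.73) and the locus LOC100154873 (-2.68) followed. CA3 is also a marker of skeletal muscle, and TPM2, the other measured member of that list, was at -0.24 and did not pass (adjusted p = 0.432). With 1 animal left out, ACAA2 kept its call only without male_high replicate 1 or male_high replicate 4, with a difference of -2.62 at its smallest. Its spread within the high-fed males (SD 2.13) leaves the variance in those fits. OVGP1 lost its call without male_low replicate 2 or male_low replicate 3. Probe sets without a symbol reached similar sizes. The largest differences among them were 7.17 ± 0.10 and -7.76 ± 0.22 (adjusted p = 3.69e-07 and 7.56e-06).

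**Figure D2:**
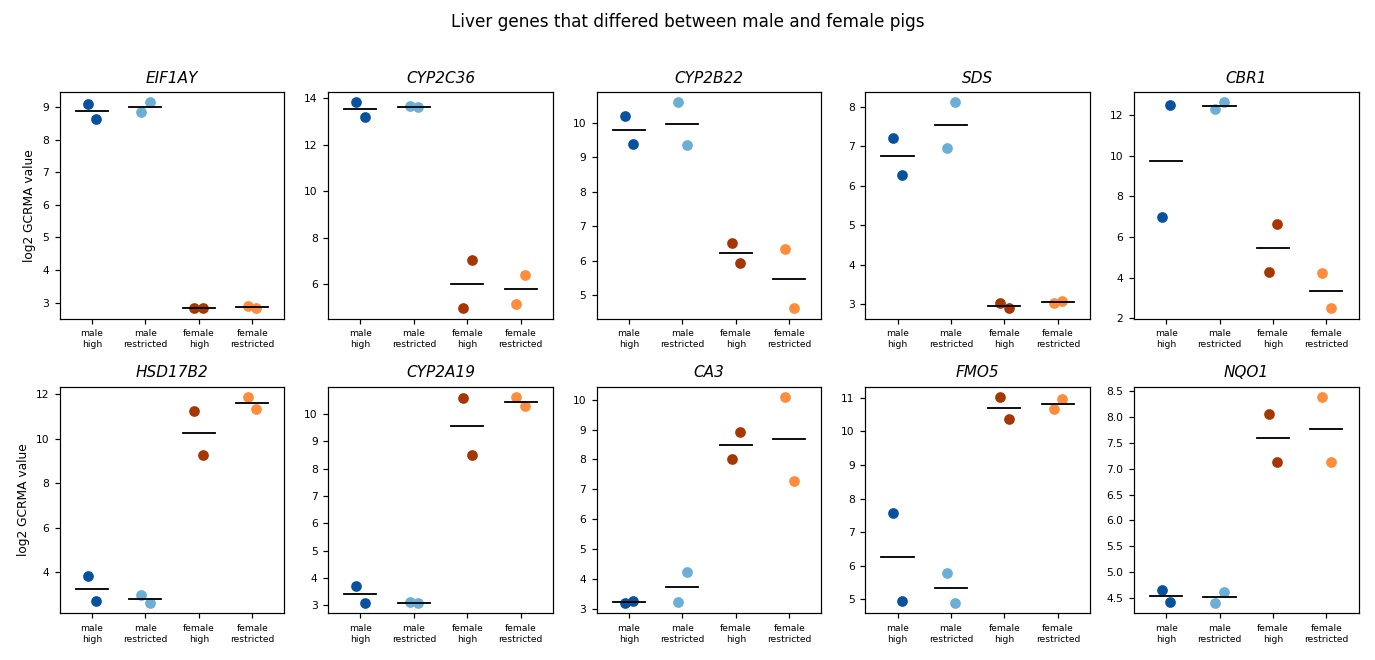
Log2 GCRMA values (vertical axis) of 10 genes in each of the 4 groups, 1 point per animal (2 per group), with a bar at the group mean; vertical scales differ between panels. EIF1AY averaged 8.94 in males and 2.85 in females, and HSD17B2 3.02 in males and 10.93 in females.

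Among the lists, 6 of 18 measured P450 enzymes passed for sex, 4 higher in males and 2 lower, the lower ones being CYP2A19 and CYP2E1 (-2.43 ± 0.26, adjusted p = 0.00505), the ethanol-inducible P450. In the list of conjugation and steroid metabolism, 3 of 30 members were higher in males and 7 were lower. SULT1E1, the oestrogen sulfotransferase, was higher (1.88 ± 0.15, adjusted p = 0.00181), while AKR1C1, an aldo-keto reductase, was lower (-2.55 ± 0.28, adjusted p = 0.00531). Adjusted over the list alone, the counts were 5 higher and 2 lower for P450 enzymes and 6 higher and 10 lower for conjugation. Over all 4757 genes, 140 were higher and 133 lower in males, counted by any of a gene's probe sets. The list counts adjusted over all probe sets, here and below, are to be read beside that share.

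Amino acid breakdown had 4 of 28 members higher in males and 2 lower. BCKDHA, a subunit of the branched-chain keto acid dehydrogenase, differed by 2.31 ± 0.10 (adjusted p = 8.34e-05), and GNMT and HPD, of methionine and tyrosine metabolism, by 1.19 ± 0.11 and 1.01 ± 0.11. Of 27 antioxidant genes, 4 were lower in males and 0 higher: NQO1, the peroxiredoxin PRDX6 (-1.31), and the metallothioneins MT3 (-1.33) and MT1A (-1.10). The sexes overlapped in both metallothioneins. MT3 was at 2.69 in female_high replicate 7 and 2.72 in male_high replicate 4, and MT1A at 13.53 in female_high replicate 7 and 13.62 in male_high replicate 1. In lipid metabolism, DGAT1 (-1.36) and DGAT2 (-1.52), which make triglyceride, and INSIG1 (-1.09), a brake on sterol synthesis, were lower in males, while the acyl-CoA synthetase ACSL3 (1.60) and the dehydrogenases ACADL (1.40) and ACADM (0.63) were higher. PDK4 (-1.85) and KHK (-1.74), the fructokinase, were lower. Of 20 genes of growth hormone, IGF and insulin signalling, EGFR passed, higher in males (0.86 ± 0.18, adjusted p = 0.0434). IGF1 was at 1.0 ± 0.29 and did not pass (adjusted p = 0.118).

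No list passed for sex in the main list test. Camera called 0 of 29, with the lowest adjusted p, 0.118, shared by the conjugation, antioxidant and hepatocyte lists (medians -0.22, -0.10 and -0.13). At an estimated correlation 0 were called as well, and fry called 2, amino acid breakdown and antioxidant genes (adjusted p = 0.00507 each). Its test of change in either direction, which sets no list against other genes, called 19 of the 29, among them amino acid breakdown (adjusted p = 1.2e-05), P450 enzymes (5.22e-05) and conjugation (0.000101). Markers of blood, macrophages, endothelium, stellate cells, bile duct and lymphocytes had 0 members past the threshold for sex. The count of 619 was 243 without the filter on low values. Without the filter 12 of the 24 genes named for the sex effect did not pass, at adjusted p from 0.052 to 0.167, and 16 of the 24 passed with each animal left out in turn. The count was 184, 220, 230, 234, 257, 341 and 368 without male_low replicate 3, female_high replicate 6, female_high replicate 7, male_low replicate 2, female_low replicate 5, male_high replicate 4 and female_low replicate 8.

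Within a feeding level the sexes were compared with 2 animals on each side. At high feeding 115 probe sets passed, 57 higher and 58 lower in males, led by CYP2C36 (7.53 ± 0.70), EIF1AY (6.04), DHRS4 (3.86), SDS (3.79), GTF2F2 (2.86), and in the other direction HSD17B2 (-7.02 ± 0.65), CYP2A19 (-6.14), MIOX (-4.60), LOC100154873 (-3.63) and SLC25A48 (-3.42). Under restriction 226 passed, 129 higher and 97 lower, led by CYP2C36 (7.87 ± 0.70), EIF1AY (6.14), CYP2B22 (4.50), SDS (4.49) and SLC1A2 (3.73), and by HSD17B2 (-8.80 ± 0.65), CYP2A19 (-7.36), SULT1A3 (-5.57), FMO5 (-5.49) and CA3 (-4.94). With 1 animal left out the count at high feeding was 22 without male_high replicate 4, 29 without either high-fed female and 50 without either restricted male. Under restriction it was 30 without male_low replicate 2, 32 without male_low replicate 3, 48 without female_low replicate 5, 50 without female_low replicate 8 and 85 without either high-fed female. At high feeding SLC25A48 lost its call in 5 of these 8 fits, SDS in 3, and CYP2C36, HSD17B2, CYP2A19 and LOC100154873 in 1 each, without male_high replicate 4. Under restriction CA3 lost it in 7, FMO5 and SLC1A2 in 6, CYP2B22 in 5, SULT1A3 in 4, and CYP2C36, SDS and CYP2A19 in 2. Without the filter on low values the counts were 41 at high feeding and 44 under restriction, and 6 and 8 of the 10 genes named at each level did not pass. With the compared arrays fitted alone they were 30 and 89, and 6 and 3 of the 10 did not pass. Of the calls with all animals, 83 were made at both levels, where independent lists would share 2.2, and all 83 had the same sign. Both levels used the same variance estimates, so their lists are not independent and 2.2 is not the overlap that chance would give. Whether the sex difference itself depended on feeding is the interaction below.

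No single gene passed the threshold for feeding. Among genes at an unadjusted p under 0.001, CRP, the C-reactive protein of the acute phase response, had the largest difference, with a log2 value of 9.41 ± 0.50 in restricted and 12.61 ± 0.76 in high-fed pigs (SD, n = 4 each), or -3.20 ± 0.34, which did not pass (adjusted p = 0.229). All 4 restricted animals lay below all 4 high-fed ones, and the difference was -3.29 in males and -3.12 in females. LBP, which binds bacterial lipopolysaccharide, was at 10.12 ± 0.60 and 12.08 ± 0.55, a difference of -1.96 ± 0.31 (adjusted p = 0.229). Limma called 0 of 11927 probe sets for feeding, with 1428 at an unadjusted p under 0.05 (622 above 0 and 806 below) where 596 would be expected by chance. Without male_low replicate 2 the 1428 became 812.

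The other values that ranked highest and did not pass were DIO1, the deiodinase that activates thyroid hormone (-1.51), GSN, the actin-severing gelsolin (1.40), EDF1 (-1.37), VKORC1 of the vitamin K cycle (-1.08), the channel subunit LRRC8A (-1.04) and the ER peroxiredoxin PRDX4 (-0.98). CYP7A1, the rate-limiting enzyme of bile acid synthesis, had a difference of -3.33 ± 1.04 (adjusted p = 0.342), with values from 2.67 to 7.40 in restricted and 5.41 to 8.77 in high-fed animals. Without male_high replicate 1, CRP passed at -3.57 (adjusted p = 0.0411), together with DEFB1 (-1.71) and 1 probe set without a symbol.

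**Figure D3:**
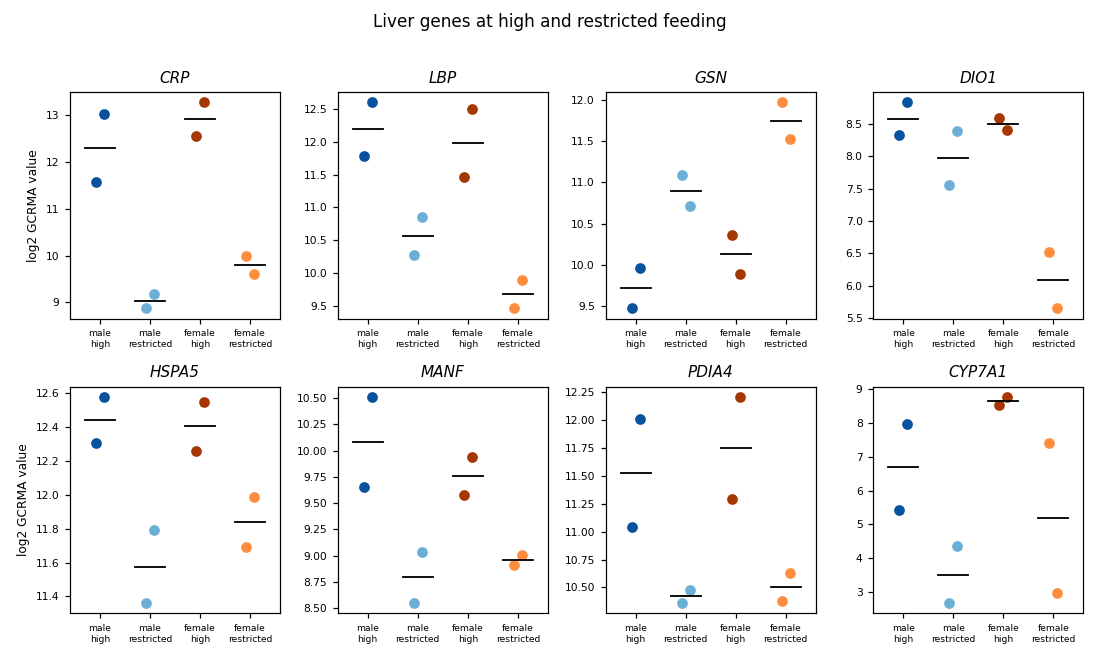
Log2 GCRMA values (vertical axis) of 8 genes in each of the 4 groups, 1 point per animal (2 per group), with a bar at the group mean; vertical scales differ between panels. CRP averaged 9.41 in restricted and 12.61 in high-fed animals, and no gene shown passed the threshold for feeding.

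As a list, heat shock and ER chaperone genes fell under restriction, with a median log2 difference of -0.36 and 27 of 33 members below 0 (camera, adjusted p = 0.0011; adjusted p = 0.389 with an estimated correlation). Over all probe sets 0 members passed, and adjusted over the list alone 8 did, all lower. They were MANF (-1.04), HSPA5 (-0.72), DNAJB11 (-1.54), PDIA4 (-1.18), HSP90B1 (-0.91), DNAJC3 (-1.31), CRELD2 (-1.68) and PDIA6 (-0.93), which fold or process proteins in the endoplasmic reticulum. All 8 were named for passing within the list, beyond the fixed rule of up to 4 members per list. The 15 ER members had a median of -0.91 and all lay below 0, while the 17 cytosolic or mitochondrial members, which hold the classical heat shock genes, had a median of -0.05 with 11 below 0, a division made after the values were seen. XBP1 was put in neither. Within the sexes camera gave the list an adjusted p of 0.0392 in males (median -0.30) and 0.000313 in females (median -0.41), and with an estimated correlation the adjusted p was 0.447 and 0.31. Leaving out each animal in turn kept the call, at adjusted p from 5.14e-05 to 0.0141, while 28 of 34 splits of the arrays into 4 and 4 gave some list a p as low.

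The mitochondrial respiratory chain list also fell, by a smaller amount, with a median of -0.12 and 48 of 54 members below 0 (camera, adjusted p = 0.00629; adjusted p = 0.698 with an estimated correlation). SDHC (-0.36), NDUFB8 (-0.32) and NDUFB4 (-0.30) had the smallest p, and 0 members passed. The call was lost without male_high replicate 4 (adjusted p = 0.0806). Macrophage markers had a median of -0.23, with SPI1 at -0.41 and CD163 at -0.67, and did not pass (adjusted p = 0.0675).

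Lists that camera placed higher under restriction were gluconeogenesis (median 0.40, 10 of 14 above 0), fatty acid oxidation (0.09, 25 of 34), amino acid breakdown (0.10, 19 of 28), circadian clock (0.23, 7 of 8) and stellate cell and matrix genes (0.13, 17 of 23). The adjusted p was 0.0361 for the first 4 and 0.0395 for the last. With an estimated correlation the adjusted p-values were 0.542, 0.698, 0.39, 0.39 and 0.698. The members with the smallest p did not pass over all genes. Among them were PCK2 (0.47) and MDH1 (-0.79) of gluconeogenesis, the fatty acid importer CPT1A (0.69), DCN (0.64) of the matrix, and the clock gene PER1 (0.72), which did pass adjusted over the list alone. Without the filter on low values all 5 of these calls ended, at adjusted p of 0.126, 0.143, 0.112, 0.112 and 0.248. They also rested on few animals. Without male_high replicate 4 the adjusted p was 0.2 for gluconeogenesis, 0.518 for fatty acid oxidation and 0.0806 for matrix genes, and without female_low replicate 8 it was 0.112, 0.32 and 0.132. Without male_low replicate 2 it was 0.0999 for the first pair and 0.117 for matrix genes, and without female_low replicate 5 it was 0.077 for amino acid breakdown and clock genes. Amino acid breakdown was also lost without male_high replicate 1 (0.0625), clock genes (0.0756) and fatty acid oxidation (0.084) without female_high replicate 7, and matrix genes without female_high replicate 6 (0.573), where their median was -0.025. The gluconeogenesis median was 0.213 without male_high replicate 4, 0.23 without male_low replicate 2 and 0.237 without female_low replicate 8. That of fatty acid oxidation was 0.021 without female_low replicate 8, 0.037 without male_high replicate 4, 0.158 without male_high replicate 1 and 0.178 without female_low replicate 5. Amino acid breakdown was at 0.03 without male_high replicate 1, clock genes at 0.151 without female_high replicate 7, and matrix genes at 0.06, 0.197 and 0.202 without female_low replicate 8, female_low replicate 5 and female_high replicate 7.

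The acute phase list was not called by camera (median -0.11, adjusted p = 0.53), and CRP and LBP passed adjusted over the list alone. By fry, acute phase (adjusted p = 0.0166), chaperone (0.0293) and antioxidant (0.0293) lists moved on balance downwards. Its test of change in either direction called glycolysis and glycogen genes (adjusted p = 0.0125), where PGK1, a glycolytic kinase, had the smallest p (-0.66) and did not pass over all genes. Fatty acid and triglyceride synthesis had a median of -0.31, with GPAM at -0.82 and ME1 at -1.19, and cholesterol synthesis one of -0.24, and neither passed (adjusted p = 0.195 and 0.753). The mean log2 value of the cholesterol genes was 9.34 in male_high replicate 1 and 9.26 in female_low replicate 8, and 9.98 to 10.80 in the other 6. That of the fatty acid and triglyceride genes was 7.62 and 7.76 in this pair, within the 7.35 to 8.44 of the others.

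With 2 animals on each side, limma called 0 probe sets for feeding in males and 0 in females, with 1118 and 945 at an unadjusted p under 0.05. The 1118 became 592 without male_low replicate 2, and the 945 became 552 without female_high replicate 7, where 596 would be expected by chance. In males the values that ranked highest after CRP were EDF1 (-1.91), SLC45A2 (1.54), VKORC1 (-1.45), PPA1 (-1.43), DHRS11 (-1.28), GATAD2A (-1.02) and POLB (-1.0), at adjusted p of 0.315 or 0.404. In females they were MIOX (-2.50), DIO1 (-2.42), GSN (1.61), ANXA1 (-1.30), PAPSS2 (1.01), ENPEP (-0.84) and ARPC2 (-0.83), at an adjusted p of 0.463. SLC45A2 was above log2 4 only in the restricted males, and ENPEP and ARPC2 only in the high-fed females. Each of these genes was kept by the filter only through that group. In males the respiratory chain list was called, with 50 of 54 members below 0 (median -0.18, camera adjusted p = 0.00732; adjusted p = 0.652 with an estimated correlation), and in females it was not (median -0.08, adjusted p = 0.126). The difference between the sexes for that list did not pass in the interaction (adjusted p = 0.563). Camera also called endothelial, immediate early and matrix genes (adjusted p = 0.00105 each) and amino acid breakdown (0.0292) as higher in restricted males, at an adjusted p of 0.447 with an estimated correlation. In females it called fatty acid oxidation (0.00168) and gluconeogenesis (0.0381) as higher and macrophage markers (0.00247) as lower, at 0.744 with an estimated correlation.

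Whether males and females responded differently to restriction was tested by the interaction. No gene passed: limma called 0 probe sets, with 644 at an unadjusted p under 0.05 and 1088 without female_low replicate 5. Of 34 splits of the arrays, 14 gave at least 644. The values that ranked highest were SLC45A2 (1.54 ± 0.26), UGP2, which makes UDP-glucose (-1.41 ± 0.19), and GATAD2A (-1.26 ± 0.23), at an adjusted p of 0.882. SLC45A2 was at 5.61 and 5.26 in the restricted males and at 3.58 to 3.99 in the other animals. It was kept by the filter at log2 4 only through that group. UGP2 averaged 12.12 in high-fed and 11.14 in restricted males, and 11.74 and 12.16 in the corresponding females.

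Several lists did shift by camera. Endothelial markers had the smallest p, with all 10 members above 0 and a median of 0.70 (adjusted p = 6.78e-05; adjusted p = 0.778 with an estimated correlation), among them FCGR2B (1.31), TEK (1.26), PECAM1 (0.81) and ERG (0.78). Above 0 were also cholesterol synthesis (0.58, adjusted p = 0.00595), immediate early genes (0.35, 0.00595), macrophage markers (0.37, 0.0151) and stellate cell and matrix genes (0.23, 0.0165), and below 0 fatty acid oxidation (-0.30, 0.0233). Each had an adjusted p of 0.778 with an estimated correlation. With the GAPDH 3' minus 5' control signal as a covariate, the calls of macrophage markers and of matrix genes were lost. Fry called 0 lists as moving one way, and in either direction it called glycolysis and glycogen genes (adjusted p = 0.000323), the list that holds UGP2. No member passed. Examples with the smallest p were EGR1 (3.90), SQLE (1.92), MRC1 (1.17), MGP (0.94) and ACADVL (-1.76). The endothelial call was kept with each animal left out in turn, at adjusted p from 5.68e-08 to 0.0272, and the other 5 were each lost without at least 3 of the animals. Macrophage markers were lost without male_low replicate 2 (median 0.04), male_high replicate 4 (0.07), female_low replicate 5 (0.24) or female_high replicate 6 (0.16), and matrix genes without male_low replicate 2 (0.16), male_high replicate 4 (0.35), female_low replicate 5 (0.02) or female_high replicate 7 (-0.04). Immediate early genes were lost without male_low replicate 2 (0.21), male_high replicate 4 (0.17), female_high replicate 7 (0.33) or female_low replicate 8 (0.42), and fatty acid oxidation without male_high replicate 1 (-0.31), male_low replicate 3 (-0.30), female_high replicate 7 (-0.28) or female_low replicate 8 (-0.22). Cholesterol synthesis was lost without male_high replicate 1 (0.245), female_low replicate 8 (0.11) or female_high replicate 6 (0.81). Leaving out both of the first 2, animals picked for their low cholesterol genes, gave it a median of -0.50 and ended the call of fatty acid oxidation (-0.13, adjusted p = 0.983).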

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

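Tests of a wrong sex label, of the ER members of the chaperone list, of other splits for that list and for the interaction, of RNA degradation by the GAPDH covariate, of the share of hepatocytes, and of the animals behind the cholesterol and endothelial lists were chosen only after the results were seen.

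For the 24 genes named for sex and the 8 named for feeding, 64 sets of 4 animals were examined for a sample far from the other 3. There were 6, where chance flags about 1 in 20. Male_high replicate 1 lay apart from the other males in CBR1 (6.99, the others 12.30 to 12.63), NRN1 (2.99, the others 7.55 to 8.05) and CYP2A19 (3.72, the others 3.08 to 3.11). CA3 was 4.24 in male_low replicate 3 and 3.20 to 3.28 in the other males. The male values of CYP2A19 and CA3 lie near background, where values are compressed, so a small gap suffices for a flag. Among females, SLC1A2 was 6.15 in female_low replicate 8 and 7.94 to 8.13 in the others, and CYP2A19 was 8.50 in female_high replicate 7 and 10.27 to 10.62 in the others.

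Probe sets that differed between the sexes numbered 619. Of the 34 splits of the 8 arrays into 4 and 4 that could be fitted with feeding in the model, 1 gave as many, the real one. The highest of the others gave 4. Among the 18 that balanced feeding between the sides, 1, the real one, gave as many. This argues against chance, which so few splits cannot exclude. A wrong sex label was argued against by EIF1AY, whose lowest male lay 5.75 above the highest female on the log2 scale. Values near the floor of the GCRMA scale did not account for the calls as a whole. Both sex means were above log2 6 in 58.5% of the called probe sets. Several of the largest named differences did have a side near the floor, such as CBR2 (1.94 in females) and HSD17B2 (3.02 in males). The size of those differences stays uncertain. A biological difference between the sexes is a hypothesis, found and tested on the same data. Males held the lower animal numbers and females the higher, and the labels gave no litter, pen or day of processing. An effect of those that followed sex cannot be told apart from it. Sequence shared between related enzymes, which was not tested, bears on which of them a probe set names.

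Lower chaperone genes under restriction had a median of -0.36, and in 28 of the 34 splits some list reached a camera adjusted p as low as their 0.0011 (2.96 as -log10, with 13.78 as the highest of the others), so chance was not excluded for the strongest of 29 lists. This list's own median was farther from 0 than in any other split (0.323), but the list was chosen for being the strongest. The shift did not rest on 1 animal, since the median nearest to 0 with an animal left out was -0.249. With the GAPDH 3' minus 5' control signal as a covariate the median was -0.374. This argues against RNA degradation only as far as that 1 control signal tracks it. A heat shock response common to all compartments stays open. The medians were -0.91 in 15 ER and -0.05 in 17 cytosolic or mitochondrial members. This gap (-0.855) cannot decide it, because the members were divided after the values were seen and 5 of the 34 splits gave a gap as large. Of the 18 splits that hold 2 animals of each sex per side, 1, the real one, did so. A response of ER protein folding to feed intake may underlie the pattern, as an untested hypothesis.

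The number of lists called for feeding, 7, was reached in 8 of 34 splits, with 9 as the highest of the others, so chance was not excluded for that count.

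Camera gave 6 lists a different response to restriction in males and females, with medians of 0.704 for endothelial markers, 0.579 for cholesterol synthesis, 0.372 for macrophage markers, 0.346 for immediate early genes, 0.234 for stellate cell and matrix genes and -0.305 for fatty acid oxidation, but with an estimated correlation each was at an adjusted p of 0.778. As many lists were called in 16 of the 34 splits crossed with sex, of which the interaction is 1, with 9 as the highest of the others, so chance was not excluded for that count. Whether the cholesterol list rests on male_high replicate 1 and female_low replicate 8 stays open, since they were picked for their low cholesterol genes, which alone lowers the median without them (-0.496). The endothelial list did not rest on 1 animal, as its median stayed at 0.411 or above with each left out. A changed share of hepatocytes against all other cells cannot be told apart from a change in endothelial cells, because the interaction of the endothelial mean minus the mean of 4 other cell type lists was 0.53, with a 95% interval from -0.11 to 1.17 that is too wide at 2 animals per group.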

How the results depend on the processing

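Leaving out both animals with low cholesterol synthesis genes and the GAPDH covariate were alternatives chosen after seeing the data, and the rest were planned. By the fixed rule, 71 differences were named for their size, apart from the list members. Those among the 71 that passed had sides that did not overlap. Leaving out an animal cannot then reverse their direction, so a kept direction is no support for them. Counting a gene once per contrast, all 71 named differences kept their direction in all 1230 refitted values, of which 138 lost the threshold and 1 gained it. For sex, 619 probe sets became 243 without the filter, which raised the number tested to 23999, 319 without both animals, and 184 to 485 with 1 animal left out. At high feeding 115 became 41 without the filter, 30 with the arrays compared alone, 50 without both animals, and 22 to 107 with 1 left out. Under restriction 226 became 44, 89, 39, and 30 to 232 in the same order. The counts of 0 held under all alternatives except 1 animal left out, which gave 0 to 3 for feeding, 0 to 2 for feeding in males and 0 to 1 for the interaction. Without male_high replicate 4, those calls were of NRN1, and without female_high replicate 7 the call was of DDX39B. Gene lists called for sex were 1 without the filter, 2 by fry, 2 without both animals, 3 with the covariate, and 0 to 2 with 1 left out, instead of 0. For feeding, 7 became 2 without the filter, 0 with an estimated correlation, 3 by fry, 11 without both animals, 12 with the covariate, and 4 to 10 with 1 left out. For the interaction, 6 became 0 with an estimated correlation, 0 by fry, and 3 to 5 with 1 left out, and cholesterol synthesis reversed to -0.496 without both animals. The counts hide calls that were lost. Of the 7 lists called for feeding, 2 lost the call with the covariate and 1 with added quantile normalization. Of the 6 for the interaction, 2 lost it with the covariate, macrophage markers and matrix genes. Causes were not tested, beyond the fewer arrays in the fits that leave animals out, where a lone animal in a group is assumed to vary like the others. The precision is limited by 2 arrays per group and by values near background.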

Other observations

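The tests of this part, apart from the splits, were chosen only after the results were seen, as were the genes named in the first paragraph.

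Some genes of lipid synthesis varied between animals of the same group. FASN, the fatty acid synthase, was at log2 6.80 in male_high replicate 1 and 5.84 in female_low replicate 8, and at 8.69 to 10.50 in the other 6 animals. SCD, the stearoyl-CoA desaturase, was at 7.23 and 7.89 in that pair and at 8.0 to 12.08 in the others. HMGCS1 (7.62 and 7.0 against 9.01 to 11.29) and SQLE (7.80 and 7.52 against 9.21 to 10.01), of cholesterol synthesis, were low in the same pair. APOA4, an apolipoprotein, was at 12.64 and 12.88 there and at 3.87 to 10.89 in the others. Not all genes of fatty acid synthesis were low in the pair: ELOVL6, a fatty acid elongase, was at 12.54 and 12.49 there and 10.37 to 12.17 in the others. The mean of the fatty acid oxidation genes was 9.97 and 10.14 in the pair and 9.50 to 9.73 in the others. The labels record nothing, such as the time since the last meal, that separates these 2 animals from the rest.

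For the 0 probe sets called for feeding and the 0 lists called for sex, other splits test nothing, since all 34 of 34 reach a count of 0, and the highest others gave 4 probe sets and 9 lists. At an unadjusted p under 0.05 the real split gave 1428 probe sets, and 1 of 34 splits gave as many, the real one, with 1332 as the highest of the others. It was 812 without male_low replicate 2, in a fit with 1 array fewer. Camera with its preset correlation called lists in many of the other splits. Some of those put most animals of a sex or a feeding level on the same side, so they are not free of the labels.

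Whether restriction moved the genes that differ by sex was examined across the 619 called probe sets. Their feeding and sex differences correlated at 0.142, across genes that are not independent replicates, which neither bears out nor rules out a small aligned effect.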
